A study of Mus musculus with 6 samples.

How the data were processed

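RNA was measured by sequencing in naive B cells from mouse spleen, in 3 libraries labelled TET2 knockout and 3 labelled TET2 wild type, numbered 2, 3 and 4 in each genotype. The mice were of the C57BL/6 strain. RNA was extracted with Trizol and an RNeasy kit and made into libraries with a stranded mRNA kit, per the labels' protocols. The labels give neither the sex of the animals nor whether each library came from a separate mouse, so p-values measure the spread between these libraries, which may be technical.

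The values used were the authors' deposited counts, whole-number fragment counts per gene name without normalization. Reads were counted with featureCounts 1.5.1 over exons of the GENCODE vM3 annotation, with paired fragments and no strand option, per the file headers. Alignment was made with STAR 2.3.0e and the build was GRCm38.p3, per the submitters' processing notes. Because a stranded library was counted without strand, reads from a gene and from an overlapping gene on the opposite strand cannot be told apart. Each gene's deposited summed exon length (in bases) was read from the same table and used only as a description. The table also held 6 columns of counts that match no sample used here, and these were left out of every step. Coordinates are those in the table (GRCm38), and gene biotypes were matched by name for 37925 of 41053 gene names.

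Library totals ranged from 35101788 to 45401781 counts, and CPM, a count relative to the library total, was computed with TMM-normalized library sizes. On this scale 3 counts in a library correspond to 0.0679 to 0.0857 CPM. Of 41053 gene names, 23019 had at least 1 count, and 13604 passed the filter on low counts (filterByExpr in edgeR, minimum count 10) and were tested. Knockout was compared with wild type by edgeR's quasi-likelihood F test with robust dispersion and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 (edgeR 4.0.16, R 4.3.3). Gene lists fixed before the data were examined, 19 of gene programmes and 9 of other cell types, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, with adjustment over all lists tested. The test was checked on simulated counts of 13604 genes with 200 changed for this comparison. It recovered 61.2% of the genes changed 1.5-fold, 97.0% of those changed 2-fold and 97.0% of those changed 4-fold, with 15 of 185 calls false. The changed genes were drawn from those with a wild-type mean of at least 2 CPM. The simulated libraries varied independently, without a difference shared by libraries of both genotypes. These shares therefore do not give the power of the real comparison, and a gene not called may still differ.

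Genes were named by a rule fixed before the data were examined. The rule takes Tet1, Tet2 and Tet3; in each direction the 12 genes past the threshold with the largest log2 change, a mean log2 CPM of at least 1 and no overlap between the genotypes; the 4 genes with the smallest p in each direction; and up to 4 called members of each list, or the 2 with the smallest p where none was called. Genes with clone or Gm names, pseudogenes and receptor gene segments were counted but not named. Other genes named in the text were chosen after their values were seen, as was the list member given as a further example. Some genes that the rule names are not reported here. A fold against a group with 0 counts was taken against a floor of 3 counts over the group. Intervals of ratios are 95% exact intervals of the group totals, and they and the floors cover counting error only.

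The alternatives fixed beforehand were other normalizations, other filters on low counts, DESeq2 1.42.0, limma-voom, a replicate block, other sets of genes, other thresholds, an estimated correlation or fry for the lists, and leaving out each library. After the data were seen, 4 more were added: the libraries numbered 2 and 3 alone, a batch term for the libraries numbered 4, that term with an estimated correlation for the lists, and Y-linked genes with Xist left out.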

Results

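Gene expression in splenic naive B cells was compared between mice lacking TET2, an enzyme that oxidizes 5-methylcytosine in DNA, and wild-type mice, with 3 libraries per genotype. The question was which genes differ in expression when TET2 is lost. Total counts in the knockout libraries numbered 2, 3 and 4 were 45401781, 41995719 and 39872470. In the wild-type libraries they were 42682762, 43343789 and 35101788. The common biological coefficient of variation over the 6 libraries was 12.4%.

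Transcripts of Tet2 (chromosome 3, 133463679 to 133544390, GRCm38) were present in every library. The level was 58.1 ± 7.47 CPM in knockout and 71.6 ± 13.5 CPM in wild type (mean ± SD, n = 3 each), a log2 change of −0.30 (SE 0.14) that was not past the threshold (edgeR adjusted p = 0.408). The exact two-sided permutation test of the CPM gave p = 0.3, where the smallest p that 3 against 3 libraries allow is 0.1. With a batch term for the libraries numbered 4, described with the principal components, the change of Tet2 was −0.29 and passed the threshold (edgeR adjusted p = 0.0420). The deleted part of the gene is not given in the labels and the counts cover all exons, so the level of Tet2 does not check the genotype labels. Tet1 differed by 0.03 (SE 0.25, edgeR adjusted p = 0.972), with the direction turned by scaling to library size only (−0.02). Tet3 differed by −0.18 (SE 0.09, edgeR adjusted p = 0.441).

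Loss of TET2 went with changed levels of 55 of 13604 tested genes, 25 higher and 30 lower in knockout (edgeR, adjusted p under 0.05). Among autosomal genes, 19 were higher and 28 lower. Rab30, a small GTPase of the Golgi, fell to 40.1% of the wild-type level, and Nmrk1, a kinase of nicotinamide riboside in NAD synthesis, to 39.3%. Cd86, a costimulatory receptor of antigen-presenting cells, rose 1.86-fold and the cell cycle regulator Ccnd2 (cyclin D2) 1.80-fold. Interferon-inducible Ifi44 and Ly6a rose 2.20-fold and 2.16-fold. The knockout libraries also held Y-linked transcripts that wild type nearly lacked, and less Xist, so genotype and sex composition differed together.

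All 55 genes separated the genotypes, with every knockout library on one side of every wild-type library. Over all tested genes, 18.5% did so, where chance gives 10% if the libraries are interchangeable. The libraries numbered 4 stood apart from the others, so 10% is not an exact reference here. At an unadjusted p under 0.05 there were 1818 genes, and 2435 when knockout libraries 2 and 4 with wild-type library 4 were set against the other libraries, which puts both libraries numbered 4 in 1 group. Of the 55, 11 were pseudogenes or had clone or Gm names. Of 217 immunoglobulin and T-cell receptor segment genes tested, edgeR called 0, DESeq2 8 and limma-voom 0, and 61 had an unadjusted p under 0.05 (edgeR). The log2 change was at least 1 for 17 of the higher genes and at most −1 for 18 of the lower ones.

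**Figure D1:**
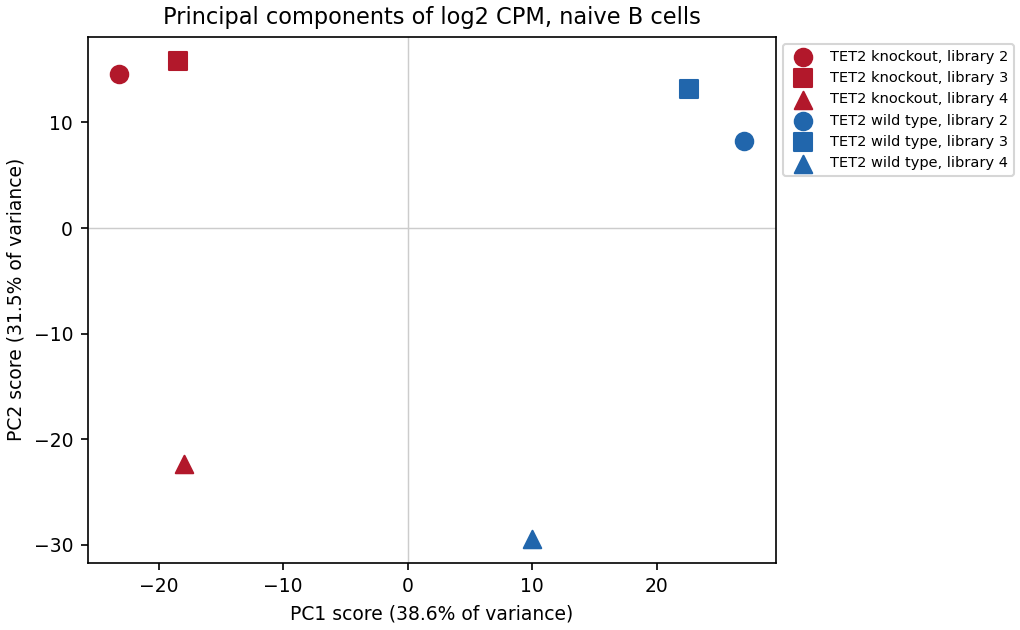
Scores of the 6 libraries on the first principal components of log2 CPM over the tested genes, PC1 with 38.6% and PC2 with 31.5% of the variance. Color gives the genotype and symbol the library number. PC1 separates the genotypes, and the libraries numbered 4 of both genotypes lie at −22.4 and −29.5 on PC2, apart from the 4 others.

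The libraries numbered 4 of both genotypes stood apart from libraries 2 and 3. PC1 of log2 CPM (38.6% of the variance) separated the genotypes, and PC2 (31.5%) separated the libraries numbered 4 from the others. With genotype in the model, 1065 genes were higher and 946 lower in the libraries numbered 4 (edgeR, adjusted p under 0.05). Heat-shock genes were among the higher ones, with Dnajb1 2.65-fold, Hsph1 3.27-fold and Hspa8 2.11-fold, and the cold-inducible Cirbp was at 0.571-fold; these genes were chosen after their values were seen. A batch term for these libraries, added after the data were seen, gave 353 genes higher and 246 lower in knockout, of which 58.9% were higher, against 45.5% of the 55. Libraries 2 and 3 alone gave 1871 higher and 1436 lower, and of the 3287 of these that were also tested with all libraries, 2144 (65.2%) had the same direction in the pair numbered 4. All 55 genes had the same direction in libraries 2 and 3 and in the pair numbered 4, which follows from their separation of the genotypes. Of these, 54 were also called with the batch term and 54 in libraries 2 and 3, in fits that reuse the same libraries. Without wild-type library 4, 630 genes were higher and 270 lower, and without knockout library 2, 9 were higher and 8 lower.

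Transcripts from the Y chromosome were found in all 3 knockout libraries and were nearly absent from wild type. Kdm5d, a histone demethylase gene of the Y chromosome, was at 23.3, 34.2 and 34.9 CPM in knockout libraries 2, 3 and 4, and at most 0.06 CPM in wild type. The ratio of total counts between the groups, with 3 counts in wild type, was 1255 for Kdm5d (95% interval 429 to 6089). For Ddx3y, an RNA helicase gene, it was 2462 (842 to 11942), for the translation factor gene Eif2s3y 889 (408 to 2423) and for Uty 719 (199 to 5946), so that all these genes rose (edgeR adjusted p at most 9.88e-05). Xist, the RNA that silences one X chromosome in female cells, fell to 56.9% of the wild-type level (log2 −0.81, SE 0.08, edgeR adjusted p = 0.00251). Its level was 57.2, 59.6 and 53.9% of the wild-type mean in knockout libraries 2, 3 and 4. The knockout libraries thus differed from wild type in sex-linked transcripts as well as genotype in every comparison given here. With the Y-linked genes and Xist left out, 20 genes were higher and 28 lower. Exons of Xist share bases with Tsix on the opposite strand, and the Y genes have similar copies on the X chromosome.

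Among the other genes that rose, Sva (chromosome 6, 42038394 to 42042851) had 573 counts in knockout and 0 in wild type, at least 188-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.000135). Acp1, a low-molecular-weight phosphatase, rose from 2.69 ± 0.160 to 6.58 ± 0.477 CPM (n = 3 each, edgeR adjusted p = 0.00736). Gpr55, a receptor for lysophospholipids, rose by 1.17 on the log2 scale, Cecr2, a bromodomain protein of chromatin remodelling complexes, by 1.06 and X-linked Chic1 by 1.02. Ifi44l rose by 0.93 (edgeR adjusted p at most 0.0440 for these 4). Ly6a, which encodes Sca-1, rose from 205 ± 44.7 to 443 ± 68.8 CPM (edgeR adjusted p = 0.0316), and was the gene not past the threshold with the batch term (0.0816). Acp1 and Gpr55 share exon bases with genes on the opposite strand, and Ly6a and the pair Ifi44 and Ifi44l belong to families of similar genes, so their levels are less certain.

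The genes that fell included Unc5cl at log2 −1.38 (SE 0.16), a death-domain protein, and Lurap1 at −1.20 (SE 0.16), which shares exon bases with Pomgnt1 on the opposite strand. Nmrk1 went from 17.9 ± 0.478 to 7.03 ± 0.236 CPM (edgeR adjusted p = 0.000504) and Rab30 from 42.7 ± 1.54 to 17.1 ± 0.875 CPM (edgeR adjusted p = 0.000135). Tmem2, a cell-surface hyaluronidase, fell by 1.09 on the log2 scale (edgeR adjusted p = 0.000778). Atp1b1, a subunit of the sodium pump, also fell by 1.09 (edgeR adjusted p = 0.00292). Plxnd1, a semaphorin receptor, fell by 1.05, the clathrin adaptor subunit Ap1m2 by 1.01 and the membrane-shaping ATPase Ehd2 by 0.99. The microtubule-associated Map10 fell to 50.0% of the wild-type level. Afap1, an actin filament protein, fell by 0.85 and the peptide transporter Slc15a2 by 0.83 (edgeR adjusted p at most 0.0440 for these 6). Slc15a2 was not past the threshold in libraries 2 and 3 alone (0.125). Of the 27 named genes past the threshold, 10 also passed it in all 6 fits that left out 1 library: Kdm5d, Eif2s3y, Uty, Ddx3y, Sva, Rab30, Nmrk1, Tmem2, Atp1b1 and Xist. The other 17 failed it in at least 1 of these fits, and 14 of them failed it in 4 or more (edgeR adjusted p up to 0.287): Ifi44, Ly6a, Cd86, Ccnd2, Cecr2, Chic1, Plxnd1, Ap1m2, Map10 and Ehd2 in 4, and Gpr55, Ifi44l, Afap1 and Slc15a2 in 5.

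**Figure D2:**
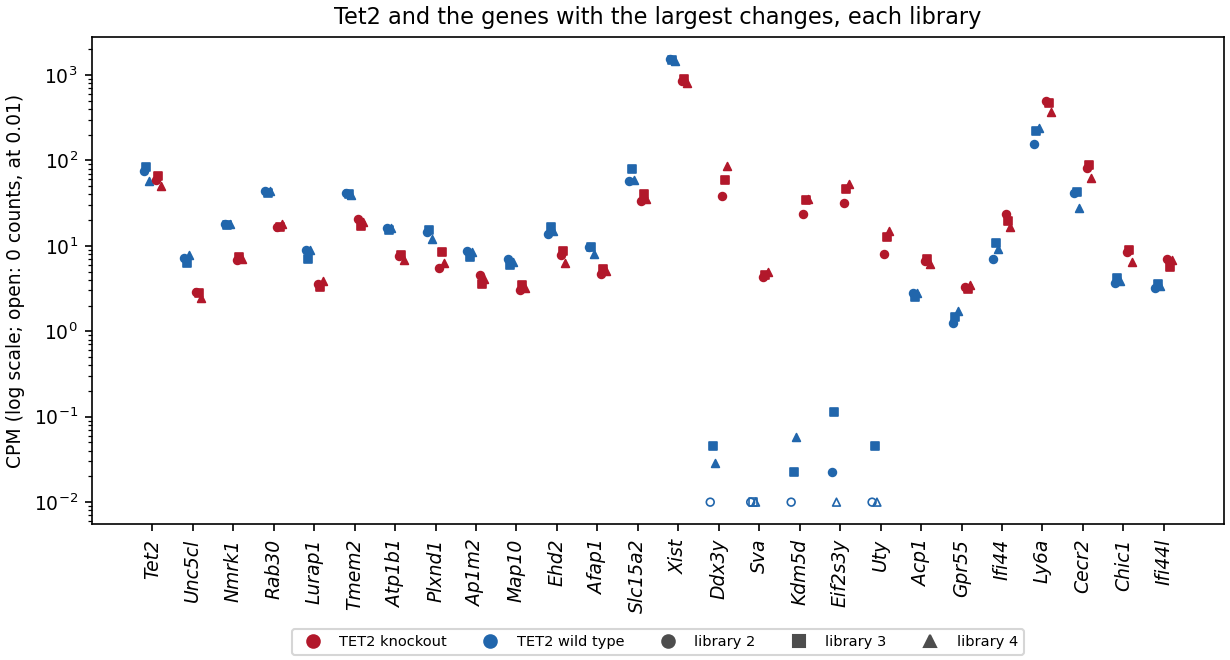
CPM of Tet2, Xist and the genes with the largest changes in each library, on a log scale, with 0 counts drawn as open symbols at 0.01. Color gives the genotype and symbol the library number. Rab30 lies at 42.7 CPM in wild type and 17.1 CPM in knockout, while Tet2 overlaps between the genotypes.

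Interferon response genes lay higher in knockout. Of 35 tested members, 34 had a positive log2 change, with a median of 0.48, and the list passed the test (camera adjusted p = 2.1e-22), but not with an estimated correlation (camera adjusted p = 0.668). Over all genes edgeR called 1 member, Ifi44, DESeq2 called 17 and limma-voom 0. With edgeR, 28 members had an unadjusted p under 0.05, and 24 were higher when adjusted over the list alone. The antiviral synthetase gene Oas3, a further member not past the threshold over all genes, was at 31.9 ± 2.48 CPM in knockout and 21.3 ± 1.96 in wild type. The mean log2 difference of the list was 0.61 within libraries 2 and 3 and 0.25 within the pair numbered 4, with 34 of 35 members positive in each. With the batch term 13 members were called higher.

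Genes of MHC class II antigen presentation and of the cell cycle shifted upward as lists. In the MHC class II list of 17, 14 members were positive with a median of 0.17 (camera adjusted p = 0.0014; 0.668 with an estimated correlation), 0 were called by edgeR over all genes, 3 by DESeq2 and 0 by limma-voom, 8 had an unadjusted p under 0.05, and 6 were higher when adjusted over the list alone. H2-DMa was at 663 ± 45.2 CPM in knockout and 522 ± 8.72 in wild type (edgeR adjusted p = 0.134), and H2-Eb2 differed by 0.34. With the batch term H2-DMa passed and H2-Eb2 did not (edgeR adjusted p = 0.0175 and 0.0508), and 2 members of the list were called higher. In the cell cycle list of 37, Ccnd2 rose (edgeR adjusted p = 0.0409), 4 members were higher when adjusted over the list alone, and the median was 0.20 (camera adjusted p = 0.00011; 0.668 with an estimated correlation). Mean log2 differences within libraries 2 and 3 and within the pair numbered 4 were 0.20 and 0.08 for MHC class II and 0.31 and 0.04 for the cell cycle, where 31 and 20 of 37 members were positive.

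Ribosomal protein genes had a median change of 0.33 over 49 members, 36 of them positive (camera adjusted p = 2.7e-06; 0.668 with an estimated correlation). Over all genes 0 were called by edgeR, 8 by DESeq2 and 0 by limma-voom, 31 had an unadjusted p under 0.05, and 15 were higher and 1 lower when adjusted over the list alone. Rpl8 differed by 0.43 (edgeR adjusted p = 0.120). The mean difference of the list was 0.20 in libraries 2 and 3 and 0.09 in the pair numbered 4, and 17 members were called higher with the batch term. Markers of B-1 and age-associated B cells had a median of 0.18 over 19 members, with 0 called by edgeR, 3 by DESeq2, 0 by limma-voom, 7 at an unadjusted p under 0.05, and 6 higher when adjusted over the list alone (camera adjusted p = 0.0062; 0.668 with an estimated correlation). Plscr1 differed by 0.91 and Cd300lf by 0.54 (edgeR adjusted p = 0.105 and 0.115). Both passed with the batch term (edgeR adjusted p = 0.0216 and 0.0186), which called 3 members of the list higher and 0 lower. The list's mean difference was 0.29 in libraries 2 and 3 and 0.25 in the pair numbered 4. Members went both ways, with 12 of 19 positive in libraries 2 and 3 and 9 in the pair numbered 4. The list was not past the threshold without wild-type library 4 or knockout library 2 (camera adjusted p up to 0.0885). Genes of B-cell identity and receptor signalling had a median of 0.07 over 29 members, with 0 called by edgeR, DESeq2 or limma-voom, 6 at an unadjusted p under 0.05, and 0 when adjusted over the list alone (camera adjusted p = 0.041; 0.668 with an estimated correlation). Their mean difference was 0.13 and 0.01 in these sets of libraries, and the call was lost in 8 of 17 other settings (camera adjusted p up to 0.215), among them those without wild-type library 2 or 4 or knockout library 2 or 3.

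The list of immediate early genes, which respond within minutes to stimulation, also held the heat-shock genes Hspa1a, Hspa1b, Dnajb1 and Hsph1. Its median was −0.31 over 28 members (camera adjusted p = 0.0062, and 0.799 with an estimated correlation). Of these, 0 were called by edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05 (edgeR), and 0 passed when adjusted over the list alone. The list stood highest in the libraries numbered 4. Its mean log2 deviation from the mean of all libraries was 0.73 in knockout 4 and 0.52 in wild type 4. It was −0.66 and −0.54 in knockout 2 and 3, and 0.05 and −0.1 in wild type 2 and 3. The mean log2 difference was −0.57 in libraries 2 and 3, with 6 of 28 members positive (camera adjusted p = 4.33e-30), but 0.21 in the pair numbered 4, with 24 positive. The list also passed with the batch term (camera adjusted p = 0.0239), but not with an estimated correlation as well (0.709). With that term 1 member was called higher and 0 lower, against the direction of the list. Egr2 differed by −0.43 and Zfp36 by −0.33 (edgeR adjusted p = 0.318 and 0.421), and the list was not past the threshold without wild-type library 4, knockout library 2 or knockout library 3 (camera adjusted p up to 0.370).

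**Figure D3:**
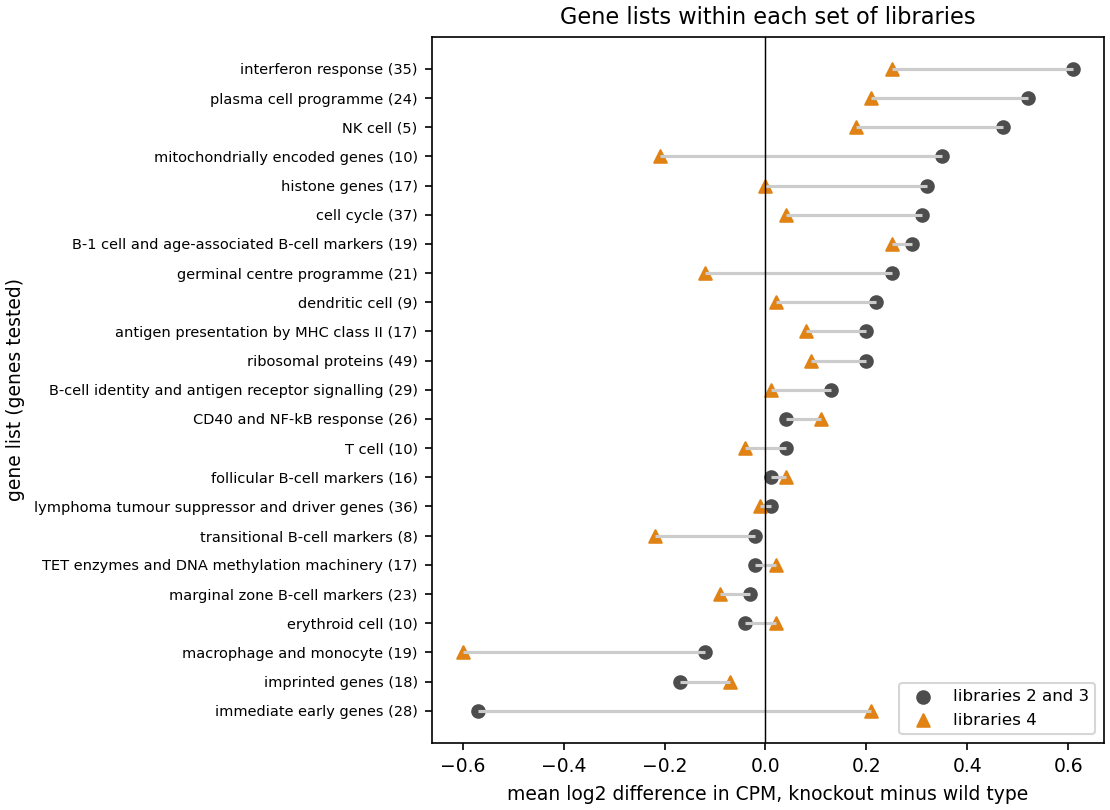
Mean log2 difference in CPM between knockout and wild type for each gene list, on the x axis, within libraries 2 and 3 (circles) and within the pair of libraries numbered 4 (triangles). Numbers in brackets are tested members. The interferon list lies at 0.61 and 0.25, and the immediate early genes lie at −0.57 and 0.21.

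Lists of B-cell subsets and programmes other than those above were not past the threshold (camera). Over all 22 lists in which edgeR called 0 of the tested members, 91 of 372 members had an unadjusted p under 0.05 (edgeR), and DESeq2 called 22 and limma-voom 0. These 22 include lists above that passed camera, with 31 of the 91 in the ribosomal list. A gene in more than 1 list counts in each. Over all tested genes, 1818 of 13604 had such a p. In the marginal zone list of 23, Plxnd1 fell, and it was the 1 member lower when adjusted over the list alone (list median −0.11, camera adjusted p = 0.523). The follicular list (median 0.07), the transitional list (−0.09) and the germinal centre list (0.21) held 0 members called by edgeR over all genes and 0 when adjusted over the list alone, with camera adjusted p = 0.694, 0.694 and 0.406. DESeq2 called 1, 0 and 1 of their members, and the batch term called 1 germinal centre gene higher and 1 lower. In the germinal centre list the mean difference was 0.25 in libraries 2 and 3 and −0.12 in the pair numbered 4. The plasma cell list had a median of 0.12 and 1 member higher when adjusted over the list alone (camera adjusted p = 0.0874), with Ighg3 at 7.18 ± 1.15 CPM in knockout and 3.78 ± 0.595 in wild type (edgeR adjusted p = 0.0928). With the batch term this list passed (camera adjusted p = 0.0358), but not with an estimated correlation as well (camera adjusted p = 0.709), and it held 2 members called higher and 2 lower. It passed in 6 of 17 other settings in all; camera adjusted p was 0.0188 without knockout library 4 and 0.569 without immunoglobulin and T-cell receptor genes, which left 19 members. In the list of CD40 and NF-kB response genes, Cd86 rose from 32.0 ± 6.54 to 59.5 ± 2.61 CPM (edgeR adjusted p = 0.0309), and 2 members were higher when adjusted over the list alone (camera adjusted p = 0.198). This list passed in 1 of 17 other settings, without knockout library 3 (camera adjusted p = 0.0178).

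The TET and DNA methylation list (median 0.01, camera adjusted p = 0.769) and the lymphoma gene list (−0.01, camera adjusted p = 0.769) held 0 genes called by edgeR over all genes. DESeq2 called 0 members of the first list and 2 of the second. When adjusted over the list alone, 0 members passed in the first, and 1 higher and 1 lower in the second. Sgk1 differed by −0.54 and Klhl6 by 0.29 (edgeR adjusted p = 0.129 and 0.157), and both passed with the batch term (edgeR adjusted p = 0.0333 and 0.0257). Imprinted genes had a median of −0.06 with 1 lower when adjusted over the list alone (camera adjusted p = 0.316), and Gnas differed by −0.86 (edgeR adjusted p = 0.0721). Gnas passed with the batch term (edgeR adjusted p = 0.0427), with a log2 difference of −1.14 in libraries 2 and 3 and −0.29 in the pair numbered 4. Exons of Gnas share bases with Nespas and another gene on the opposite strand, so its level is less certain. Histone genes (0.13) and mitochondrially encoded genes (0.16) held 0 called members and 0 when adjusted over the list alone (camera adjusted p = 0.424 and 0.188). Mitochondrial transcripts differed by 0.35 in libraries 2 and 3 and by −0.21 in the pair numbered 4, and their list passed in 2 of 17 other settings, without wild-type library 4 (camera adjusted p = 0.00107) and in libraries 2 and 3 alone (0.000469). Of 35 germline genes 4 could be tested, with 0 called by edgeR over all genes and 0 when adjusted over the list alone.

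Of 62 tested markers of other cell types, 52 had a mean under 10 CPM in both genotypes. The exceptions included Pecam1, at 384 ± 66.2 CPM in knockout and 352 ± 28.0 in wild type, Tfrc and Ly6a. The macrophage and monocyte list had a median of −0.28 over 19 genes (camera adjusted p = 0.0546, past the threshold in 5 of 17 other settings). Over all genes 0 were called by edgeR, 1 by DESeq2 and 0 by limma-voom, and 0 passed when adjusted over the list alone. Lyz2 was at 5.97 ± 0.908 CPM in knockout and 9.01 ± 1.47 in wild type (edgeR adjusted p = 0.221). In the other direction, Emr1 was at 12.3 ± 2.05 and 9.03 ± 0.696 CPM (edgeR adjusted p = 0.254). The T cell list (median −0.01, 1 lower when adjusted over the list alone), the NK cell list (0.41), the dendritic cell list (0.10) and the erythroid list (−0.15) held 0 members called by edgeR over all genes, with camera adjusted p = 0.769, 0.299, 0.424 and 0.629. In the last 3 of these lists, 0 members passed when adjusted over the list alone. In the T cell list DESeq2 called 1 member, and the batch term 1 higher and 1 lower. In the dendritic cell list the batch term called 1 member higher. Of the progenitor list 3 genes were tested, of which Ly6a rose, and 1 was higher and 1 lower when adjusted over the list alone. The megakaryocyte and stromal lists had 3 tested genes each, 0 called by edgeR and 0 when adjusted over the list alone, and none of the 19 neutrophil genes had enough counts to be tested.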

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

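The tests with the libraries numbered 2 and 3 alone, with a batch term and without Y-linked genes and Xist were chosen after the data were seen. Against 25 genes higher and 30 lower in knockout, no filter on low counts gave 160 and 102, DESeq2 197 and 152 with all 55 shared, an adjusted p under 0.1 gave 38 higher, and a log2 change of at least 1 left 18 lower. The batch term gave 353 and 246, and libraries 2 and 3 alone 1871 and 1436. The cause of the larger counts with DESeq2 or no filter was not tested; the batch term takes the difference of the libraries numbered 4 out of the spread. Over the fits that left out 1 library, counts ranged from 9 to 630 higher and 8 to 270 lower, and lists from 4 to 8, against 7, with fewer samples in each fit. A replicate block gave 35 higher and 50 lower. Same-numbered libraries deviated from their group means with correlations of 0.0857 (2), 0.220 (3) and 0.394 (4). Knockout 3 and 4 correlated best with the wild-type library of their own number, and knockout 2 with wild type 3 (0.239). The group means include the libraries numbered 4, so the deviations of libraries 2 and 3 share that difference. These correlations therefore cannot show whether libraries numbered 2 or 3 are paired. Lists past the threshold were 0 of 23 with an estimated correlation (1 at an unadjusted p under 0.05), 0 with fry (4) and 0 with the batch term and an estimated correlation (0). Of the values of named genes under the alternatives, 1175 kept direction and side of the threshold, 89 lost it, 108 gained it and 3 reversed, all of Tet1: −0.02 with library size only, −0.12 without wild-type library 4 and −0.18 without knockout library 2, against 0.23 without knockout library 4. The cause was not tested. Other counts stayed within 1.5 times. Scaling to library size only moved the median of all genes by −0.05. Genes with under 3 counts in a library cannot be told from 0 at this depth.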

Other observations

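The tests of the sex-linked transcripts, the interferon list, the libraries numbered 4 and the splits with a batch term were chosen after the results were seen, and the other splits before.

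With the batch term, genes of several further kinds passed the threshold. Havcr1, which encodes the phosphatidylserine receptor TIM-1, rose by 0.99 on the log2 scale, from 1.36 ± 0.273 to 2.71 ± 0.422 CPM (n = 3 each, edgeR adjusted p = 0.0246). Pigr, the transport receptor of polymeric immunoglobulin, fell to 49.9% of the wild-type level (edgeR adjusted p = 0.0286). Tenm4, which shares exon bases with a gene on the opposite strand, fell to 48.1% (edgeR adjusted p = 0.00811). Of the switched heavy chain constant genes, Ighg3 rose by 0.93 and Ighg2b by 1.52 with this term (edgeR adjusted p = 0.00990 and 0.0294), and without it neither was past the threshold. Near Tet2, within 25 Mb, 2 of 149 tested genes were called, Ifi44 and Ifi44l, against 53 of 13455 elsewhere (Fisher's exact test, two-sided p = 0.122). Called genes also lay close together elsewhere. The 4 called of 475 tested on chromosome 19, Nmrk1 and Tmem2 among them, lay between 17326141 and 21858327. The 2 called on chromosome 16, Cd86 and Slc15a2, lay between 36603869 and 36784962. On chromosome 6, 7 of 718 tested genes were called. Of these, Plxnd1, Cecr2 and Ccnd2 lay between 115954811 and 127151048, while Sva lay apart at 42038394. X-linked Chic1 and Xist lay between 103356476 and 103483217. Whether DNA at these places differed between the groups was not tested.

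All 3 knockout libraries held Y-linked transcripts together with 53.9% or more of the wild-type level of Xist. This argues against a whole male library in place of a female one, which would hold almost no Xist. Xist switched on in male cells would silence their single X chromosome, but the median log2 change of X-linked genes other than Xist was 0.02. A mixture of female and male cells in each knockout library may explain the pattern: 4 X-linked partners of the Y genes (Kdm6a, Kdm5c, Ddx3x and Eif2s3x), which escape silencing in female cells, had a median of −0.19, none past the threshold (edgeR). The Y-linked levels did not mirror Xist closely. In knockout libraries 2, 3 and 4, Ddx3y was at 38.0, 58.6 and 85.9 CPM and Uty at 8.04, 12.5 and 14.8 CPM. Xist was at 57.2, 59.6 and 53.9% of the wild-type mean in these libraries, so the share of male cells alone would not set both. Whether cells were pooled from mice of both sexes is not given in the labels.

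By design, handling shared by the libraries numbered 4 could not produce the mean difference of the interferon list within libraries 2 and 3 (0.61). This does not cover handling that differed between the genotypes within libraries 2 and 3, which was not tested. The immediate early list differed by −0.57 in those libraries and by 0.21 in the pair numbered 4. The mean difference of the interferon list within the pair numbered 4 was 0.25, from 1 library per genotype and so without a spread between replicates. More macrophages or monocytes would raise their own genes, whose median was −0.28, with −0.31 for C1qa, C1qb, C1qc and Lyz2, although Emr1 differed by 0.45 in the other direction. The dendritic cell list of 9 genes had a median of 0.10 and was not past the threshold (camera adjusted p = 0.424), which does not exclude a larger share of these cells. The sex of the animals and the loss of TET2 cannot be told apart as sources, because 0 knockout libraries lacked Y-linked transcripts. In the 10 splits of the libraries, too few for a share under 0.05, the p of the list was 8.96e-24 for genotype and at smallest 4.54e-12 in another split, with 8 of the 9 others under 0.05 (camera, unadjusted). Each of these others leaves 2 libraries of the same genotype together in each group, so they hold part of any genotype difference. An effect of TET2 loss on interferon-inducible genes is therefore a hypothesis that these libraries leave open.

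The libraries numbered 4 of both genotypes differed from the others in 2011 genes (edgeR). Lower depth does not account for this: after thinning all libraries to 1 total, the pair numbered 4 differed by a chi-square of 12.1 per gene, against 35.3 to 46.3 between each of them and its own group. Shared heat or handling stress may contribute, since 4 of 4 heat-shock genes (Hspa1a, Hspa1b, Dnajb1 and Hsph1) were higher in both libraries numbered 4 than in every other library. Without thinning, the pair numbered 4 differed by 12.7 per gene. That is near the 11.6 between knockout 2 and 3 and the 11.9 between wild type 2 and 3. Knockout 2 or 3 against wild type 2 or 3 differed by 38.6 to 76.5. By this measure the genotypes differed far less in the pair numbered 4 than in libraries 2 and 3. No date or batch is given in the labels.

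The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The genotype split gave 55 called genes and the highest of the others 0, so 1 split of 10 gave as many. For lists, 3 splits of 10 gave as many as the 7 found for genotype, and the highest other gave 9. Of the 6 splits with 1 library numbered 4 in each group, also too few, 1 gave as many as the 599 genes called with the batch term, and the highest other gave 0. In every other split both groups hold libraries of both genotypes, so differences between the genotypes add to the spread within groups. This lowers the number of genes called there, so the values of 0 are no measure of chance.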
